A study of Homo sapiens with 6 samples.

How the data were processed

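RNA was measured in human neurons of the excitatory, glutamate-releasing type, which the supplier (FujiFilm Cellular Dynamics) derives from induced pluripotent stem cells, here of wild-type genotype. The labels name 3 untreated samples and 3 samples treated with an oligonucleotide of CA repeats at 5 µM, written CAn here. No label gives the length, chemistry or delivery of the oligonucleotide, or the time in culture. Per the labels' protocols, total RNA was isolated on silica columns and stranded libraries were made after removal of ribosomal RNA, so that RNA without a poly(A) tail was sequenced too. No label says whether the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

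The submitters' processing notes name bcl2fastq, Trimmomatic 0.32, STAR 2.7.6a, RSEM 1.3.3 and the genome build GRCh38, without roles or settings. The deposited table holds 16952 genes and 12 columns of values. The first 6 columns are estimated counts per gene, as the authors deposited them, rounded to whole numbers. The smallest deposited count was 10 in each library, so genes under that count in any library, including any that were switched on or off, were not analysed here. The other 6 columns hold the authors' normalized values, a signal that equals each deposited count divided by a factor that differs between genes and libraries. The log2 factor averaged 0 over the 6 libraries for every gene (largest deviation 4e-10), which is the form of an offset for library size and transcript length. How that factor was made is not given in the sources used here. Whether the counting used the strand of the reads is not given either.

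The main comparison was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, CAn against untreated over all 6 libraries, with trimmed-mean (TMM) scaling, default filtering by expression, no covariate and a Benjamini-Hochberg threshold of 0.05. The filter removed 0 genes. Levels are given as CPM (counts scaled to a common library total) after the same scaling, and standard errors (SE) of log2 fold changes were derived from the F statistic. Sets of genes were tested with camera at a preset correlation of 0.01, over 34 lists fixed before the data were examined. Of these, 32 had at least 5 listed genes. MATR3 stands in 2 rows of the table, and both were used. Gene coordinates come from RefSeq on GRCh38.p14, where 15125 of the 16952 genes (89.2%) were found by symbol or unambiguous synonym. No genome sequence was used here.

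The genes named follow a rule fixed before the data were examined. It takes TARDBP, STMN2 and UNC13A, members of the TDP-43 target list past the threshold, and up to 12 genes with the largest rise and 12 with the largest fall among genes past the threshold. These needed a mean of at least 1 CPM, every treated library on one side of every untreated one, and a symbol that is not that of a clone, a long noncoding locus or a pseudogene. With no gene past the threshold, the rule takes the 5 genes with the smallest p in each direction, as values only. For gene lists it takes up to 4 members with the smallest p. Some genes that the rule takes are not reported here. The rule was applied again to the fit without CAn replicate 2, over its 5 libraries. Leaving out each library in turn was fixed beforehand. The choice to describe the fit without CAn replicate 2 in detail was made after its correlation with the other libraries had been seen.

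Alternatives fixed beforehand were other scalings, filters and thresholds, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, a trend on gene span removed by an offset, and the 6 fits that each leave out 1 library. Alternatives added afterwards were limma-voom with a quality weight per library, the authors' deposited factors as offsets in edgeR, and every alternative repeated without CAn replicate 2. The deposited factors were also compared between the groups on the log2 scale with limma, after each library's median was subtracted, as a proxy for the effective transcript length of each gene. Their effects stand in the closing section.

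The fit was tested on simulated counts with the real means and library sizes, with 200 changed genes per simulation over 5 simulations, in which the deviations of CAn replicate 2 were reassigned among genes of similar expression. Genes were drawn independently, with the dispersions of the fit without CAn replicate 2. Correlation between genes was thus not simulated, and the shares found and false calls hold only for that setting. With all 6 libraries, 0% of genes changed 1.5-fold, 14.6% of those changed 2-fold and 60.3% of those changed 4-fold were found. There were 0 false calls among 248. In the fit without CAn replicate 2 the shares were 49.9%, 68.7% and 91.2%, with 47 false calls among 745.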

Results

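The dataset holds RNA levels of cultured human glutamatergic neurons, untreated or treated with 5 µM of an oligonucleotide of CA repeats. The series title sets the treatment against mis-splicing in TDP-43 pathology. TDP-43 is an RNA-binding protein, encoded by TARDBP, that binds UG-rich RNA and represses cryptic exons. Counts per gene report the amount of RNA and not its splicing. The untreated libraries held 108312268, 103057249 and 112528400 assigned counts, and the CAn libraries 101516583, 68193217 and 108385576, over 16952 genes. The median gene had between 1145 and 1842 counts per library, so counting error was small for most genes beside the spread between samples.

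CAn replicate 2 stood apart from the remaining libraries. The median Pearson correlation across genes of its log2 CPM with the others was 0.9308, against 0.9817 to 0.9865 for the other 5 libraries, where genes are not independent replicates. The first principal component carried 62.7% of the variance and placed this library at 102, with the other 5 between -24.85 and -17.06. The second component, with 12.5% of the variance, placed CAn replicates 1 and 3 at -18.7 and -21.23, below the untreated libraries at -3.501 to 40.89, and CAn replicate 2 at 0.2057, within the untreated range. The biological coefficient of variation fitted by edgeR was 30.6% over all 6 libraries and 17.6% without CAn replicate 2. No pair of replicates agreed within sampling noise. The abundant noncoding RNAs RN7SL1, RN7SL2 and RN7SK together took 16.33%, 10.28% and 12.2% of the counts in the untreated libraries, and 10.27%, 7.69% and 9.819% in the CAn libraries.

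**Figure D1:**
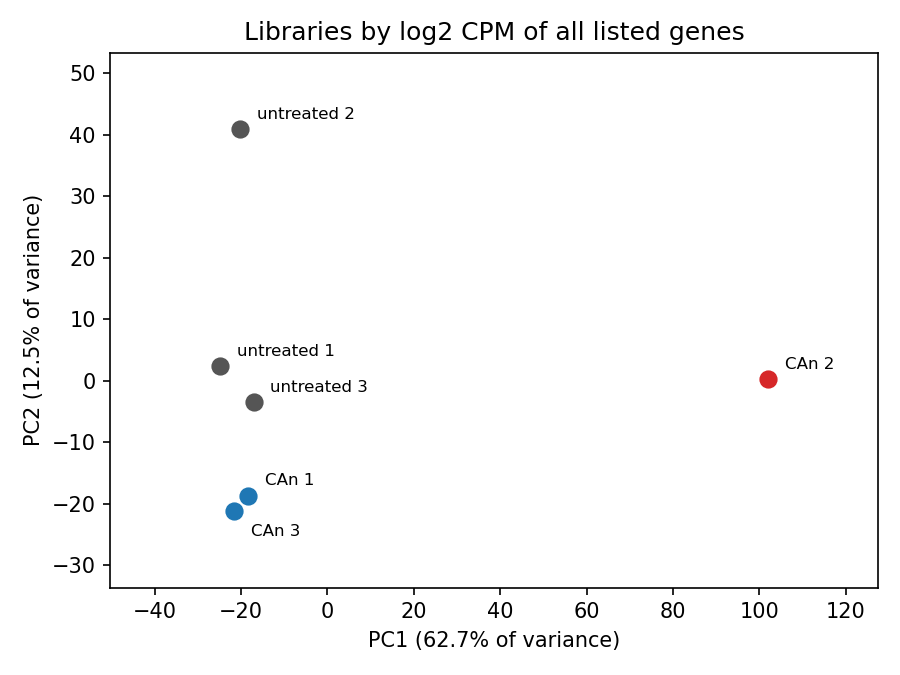
Libraries placed by the first and second principal components of log2 CPM over all listed genes, with the share of variance on each axis. CAn replicate 2 (red) lies at 102 on the first component, and the untreated libraries (grey) and CAn replicates 1 and 3 (blue) lie between -24.85 and -17.06.

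The comparison of CAn-treated with untreated neurons asked which genes changed in amount. The gene with the smallest p was OXCT1, which encodes the mitochondrial transferase that activates ketone bodies for oxidation, on chromosome 5 from 41730065 to 41870425. It had 182.2 ± 2.32 CPM untreated (SD, n = 3) and 70.05 ± 19.6 CPM with CAn, in single libraries 79.63, 47.52 and 83.0 CPM. PAK1, a kinase that acts downstream of Rac and Cdc42 on the actin cytoskeleton, had 101.0 ± 2.01 CPM untreated and 59.34 ± 4.78 CPM with CAn. NPTX2, a secreted pentraxin that gathers AMPA receptors at synapses, had 67.07 ± 1.22 and 46.68 ± 2.23 CPM, and UBE4A, a ubiquitin ligase, 85.3 ± 4.77 and 56.5 ± 5.38 CPM. Higher with CAn were the values of FABP3, a fatty acid carrier (24.3 ± 2.41 and 44.76 ± 2.31 CPM), and of GRM5, a metabotropic glutamate receptor (29.77 ± 4.2 and 50.6 ± 3.82 CPM). The same held for NWD2 (26.33 ± 1.4 and 39.03 ± 1.17 CPM), IL18BP, which binds the cytokine IL-18 (5.57 ± 0.405 and 10.68 ± 1.7 CPM), and TNNI1, a troponin of slow muscle (3.891 ± 0.439 and 8.22 ± 1.25 CPM). For each of these genes every CAn library lay on the same side of every untreated library.

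None of these differences passed the main test, that of edgeR, over all 6 libraries. The edgeR test called 0 of 16952 genes after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.82. At an unadjusted p under 0.05 it found 671 genes, where chance alone gives 848. DESeq2 called 19 genes (13 higher, 6 lower), limma-voom 0, and limma-voom with a quality weight per library, added after the data were seen, 47 (21 higher, 26 lower). The DESeq2 calls held every gene of the preceding paragraph except UBE4A (DESeq2 adjusted p = 0.0603). TNNI1 and IL18BP passed there (DESeq2 adjusted p = 0.00753 and 0.0206) and with library weights (limma adjusted p = 0.0387 and 0.0379). Without CAn replicate 2 they did not pass (edgeR adjusted p = 0.0884 and 0.0917). Leaving out CAn replicate 2 gave 44 genes (14 higher, 30 lower, 1852 at an unadjusted p under 0.05), while leaving out any other library gave 0. The groups did not overlap for 2306 genes, or 13.6%, where chance gives 10%.

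In the fit without CAn replicate 2, OXCT1 fell 2.24-fold, by 1.16 ± 0.06 on the log2 scale (SE, edgeR adjusted p = 4.71e-07). PAK1 fell by 0.83 ± 0.07 (adjusted p = 8.49e-05). FABP3 rose by 0.92 ± 0.10 (adjusted p = 0.00099), and GRM5 by 0.75 ± 0.12 (adjusted p = 0.013). These genes, with NPTX2 and NWD2, were among the 7 called both there, among 44, and by DESeq2 over all 6 libraries, among 19. The DESeq2 fit held the same 5 libraries beside CAn replicate 2, so this overlap is not separate support. All 7 were also called with library weights, in the same direction. Of the 44 genes, 33 were called with library weights. That fit gave CAn replicate 2 a weight of 0.0756, against 1.39 to 1.98 for the other libraries. It thus came close to leaving that library out, and its calls are not separate support. In CAn replicate 2 itself, which had no part in that fit, 30 of the 44 genes (68.2%) differed from the untreated mean in the called direction. That share was 61% ± 7.69 (SD) over 50 simulations with no effect and with genes drawn independently, since the same untreated libraries serve both sides. PAK1 lies on chromosome 11 from 77322017 to 77530009, FABP3 on chromosome 1 from 31359588 to 31373076 and GRM5 on chromosome 11 from 88504642 to 89065982.

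**Figure D2:**
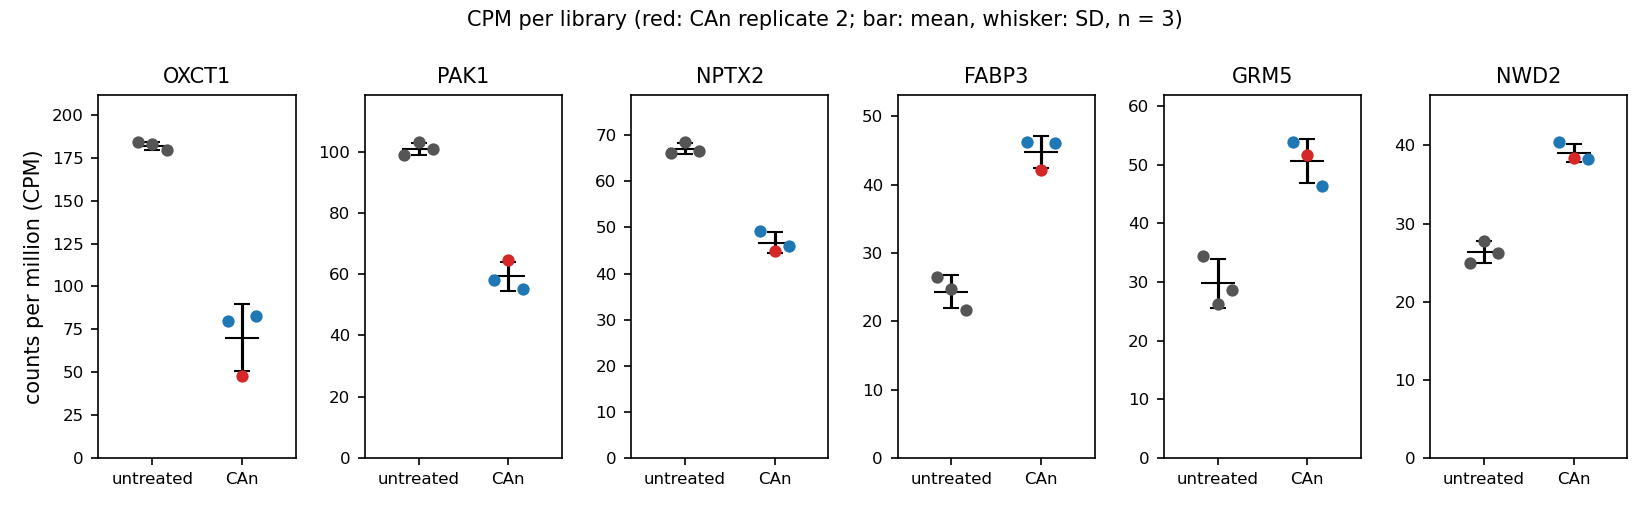
CPM per library of 6 of the 7 genes called by DESeq2 over all 6 libraries, by edgeR without CAn replicate 2 and by limma-voom with library weights, 1 panel per gene with its own axis from 0. Points are libraries, bars are means and whiskers are SD (n = 3 per group), with CAn replicate 2 in red. In OXCT1 the untreated libraries average 182.2 CPM, and the CAn libraries lie at 79.63, 47.52 and 83.0 CPM.

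Among the other genes that fell without CAn replicate 2, HSPA6, a heat-inducible chaperone, fell by 1.52 ± 0.22 (SE, log2; edgeR adjusted p = 0.00831) from 10.55 ± 2.34 CPM untreated (SD, n = 3). ERI3, an exonuclease, fell by 0.70, the small Cajal body RNA SCARNA7 by 0.67, and ARPC4, a subunit of the actin-nucleating ARP2/3 complex, by 0.63. The orphan receptor GPR173 fell by 0.59, BMS1, a ribosome assembly factor, by 0.57 and COX8A, a subunit of cytochrome c oxidase, by 0.55. The neuronal sodium channel SCN3A fell by 0.46 (adjusted p = 0.00346). Among genes that rose, NCK2, an adaptor protein, rose by 0.63, IRS4, an insulin receptor substrate, by 0.63, CPNE3 by 0.55 and the matrix proteoglycan VCAN by 0.51. MVD and HMGCS1 of the mevalonate pathway rose by 0.53 and 0.33, and the fatty acid desaturase SCD by 0.31. Among these, CAn replicate 2 went against the call for GPR173, COX8A, CPNE3 and HMGCS1. For HMGCS1 it held 550.3 CPM, against 1047 and 1049 CPM in the other CAn libraries and 835.9 ± 19.8 CPM untreated.

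Some called genes share sequence with near-identical copies, and their values are uncertain. SERF1A rose by 1.08 and its copy SERF1B fell by 0.95 in the fit without CAn replicate 2, while their summed counts differed by -0.06 ± 0.09 (SE, log2; edgeR adjusted p = 0.857). BOLA2B fell by 0.72 and CBWD6 rose by 0.58, and both belong to families of recent duplicates, as does HSPA6. The number of calls depended on the libraries. When a second library was left out, it was 10 without CAn replicate 1, 28 without CAn replicate 3 and 74 without untreated replicate 3. With the authors' factors as offsets, OXCT1 alone passed, and the differences of SERF1A, SERF1B and VCAN became 0.50, -0.39 and 0.32. Those of PAK1, UBE4A and MVD also shrank, to -0.59, -0.38 and 0.40, while that of FABP3 went from 0.92 to 1.06.

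TARDBP had 138.7 ± 6.49 CPM untreated (SD, n = 3) and 116.3 ± 8.07 CPM with CAn. The log2 difference was -0.25 ± 0.12 over all 6 libraries (SE, edgeR adjusted p = 0.82) and -0.21 ± 0.07 without CAn replicate 2 (adjusted p = 0.256). With the authors' factors as offsets it was -0.09 over all 6 (adjusted p = 0.906) and -0.26 without CAn replicate 2 (adjusted p = 0.601). STMN2, whose full-length mRNA is lost when TDP-43 is depleted in human neurons, had 2219 ± 61 and 2331 ± 225 CPM, a difference of 0.07 ± 0.12 over all libraries (SE, log2; edgeR adjusted p = 0.861). It was 0.15 ± 0.05 without CAn replicate 2 (adjusted p = 0.327), and 0.49 over all libraries with the authors' factors as offsets (adjusted p = 0.833). With these offsets and without CAn replicate 2 it was 0.36 (edgeR adjusted p = 0.16). UNC13A, which gains a cryptic exon under the same condition, had 346.6 ± 6.59 and 483.4 ± 198 CPM. That mean was set by CAn replicate 2 at 712.1 CPM, beside 364.9 and 373.2 CPM in the other CAn libraries. None of the 37 listed genes known to respond to TDP-43 depletion passed in either fit, over all genes or adjusted over the list alone. The smallest unadjusted p over all 6 libraries was that of ADCY1 (0.61 ± 0.25, SE, log2; edgeR adjusted p = 0.82). CAn replicate 2 lay 1.12 above the untreated mean for this gene, and without it the difference was 0.27 ± 0.08 (edgeR adjusted p = 0.231).

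The gene lists asked whether functional groups moved together. The integrated stress response list, of genes driven by ATF4 and CHOP, lay higher with CAn: 24 of 29 listed genes had higher values, with a median log2 difference of 0.35 (camera adjusted p = 0.000124; adjusted p = 0.796 with an estimated correlation). Its medians against the untreated mean were 0.45, 0.37 and 0.08 in the CAn libraries, and -0.05 to 0.02 in the untreated ones. Without CAn replicate 2, 26 of 29 genes were higher (camera adjusted p = 1.18e-09; adjusted p = 0.70 with an estimated correlation), 0 passed over all genes and 15 passed adjusted over the list alone. The call rested on CAn replicate 1: without that library the camera adjusted p was 0.313, and it was 0.371 with CAn replicate 2 left out too. Without CAn replicate 2, the serine synthesis enzyme PSAT1 differed by 0.67 ± 0.13 (SE, log2; edgeR adjusted p = 0.0607 over all genes), the tRNA exporter XPOT by 0.31, the receptor VLDLR by 0.34 and the cystine carrier SLC7A11 by 0.65.

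Markers of GABA-releasing neurons, a class the culture can hold beside the glutamatergic one, were higher for 11 of 11 listed genes over all 6 libraries. The median log2 difference was 0.43 (camera adjusted p = 0.000221; adjusted p = 0.796 with an estimated correlation). When CAn replicate 2 was left out, 4 of them passed adjusted over the list alone, among them GAD1, SST and GAD2 with differences of 0.46, 0.62 and 0.29, and 0 passed over all genes. The medians of this list against the untreated mean were 0.43, 0.57 and 0.29 in the CAn libraries. In the untreated libraries they spread from -0.15 to 0.18. Nuclear genes of oxidative phosphorylation were lower for 31 of 36 members over all 6 libraries, with a median of -0.24 (camera adjusted p = 2.92e-06; adjusted p = 0.797 with an estimated correlation). They were lower for 26 of 36 without CAn replicate 2 (camera adjusted p = 0.000182; adjusted p = 0.70 with an estimated correlation), with COX8A past the threshold over all genes. CAn replicate 2 set the size of the shift: the CAn medians were -0.121, -0.617 and -0.0944, and the median log2 difference without it was -0.115. That call ended when untreated replicate 1 was left out too (camera adjusted p = 0.187). Among the other members with the smallest p, ATP5PO differed by -0.35, NDUFA4 by -0.26 and NDUFV2 by -0.26.

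A further 3 lists were called over all 6 libraries, and CAn replicate 2 set their medians. These were the TDP-43 depletion targets, the glutamatergic markers and the splicing factors. For the TDP-43 targets the CAn medians were -0.02, 0.43 and 0.02, for glutamatergic markers -0.01, 0.76 and 0.12, and for splicing factors -0.05, -0.56 and -0.02. Their camera adjusted p values were 0.0109, 0.017 and 0.0215, and 0.797, 0.796 and 0.796 with an estimated correlation. When CAn replicate 2 was left out they were 0.718, 0.146 and 0.243. The call of the splicing factors also ended without untreated replicate 1 (camera adjusted p = 0.0655).

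A further 4 lists were called without CAn replicate 2, all with an adjusted p of 0.70 with an estimated correlation. Cholesterol synthesis genes were higher for 18 of 22 members (camera adjusted p = 1.07e-05), of which HMGCS1 and MVD passed over all genes and 5 passed adjusted over the list alone, STARD4 and CYP51A1 among them. The CAn medians of this list were 0.151, -0.172 and 0.0757, so CAn replicate 2 went against the call. Over all 6 libraries its camera adjusted p was 0.611. All 13 mRNAs of the mitochondrial genome were lower (camera adjusted p = 0.000118, and 0.0893 with the replicate number as a block), 0 of them past the threshold either way. The call ended when CAn replicate 1 (camera adjusted p = 0.424) or untreated replicate 2 (0.163) was left out too. CAn replicate 2 had a median of 0.65 for these mRNAs, beside -0.31 and -0.07 in the other CAn libraries and -0.16 to 0.25 in the untreated ones. Over all 6 libraries their median was above 0 and the direction given by camera was below. Genes of the unfolded protein response had CAn medians of 0.083, -0.174 and 0.00374 (camera adjusted p = 0.724 over all 6 libraries). Without CAn replicate 2, which went the other way, they were higher for 13 of 21 members (camera adjusted p = 0.00216). The chaperones HSP90B1, HSPA5 and CALR passed adjusted over the list alone with SEL1L. Leaving out CAn replicate 1 too ended this call (camera adjusted p = 0.169). Genes of glycolysis and hypoxia were lower for 18 of 25 members (camera adjusted p = 0.0206), with TPI1 and ENO2 at -0.24 and -0.22. This call ended without scaling beyond library size (camera adjusted p = 0.0787), and when untreated replicate 1 (0.235), CAn replicate 1 (0.169) or CAn replicate 3 (0.0645) was left out too.

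**Figure D3:**
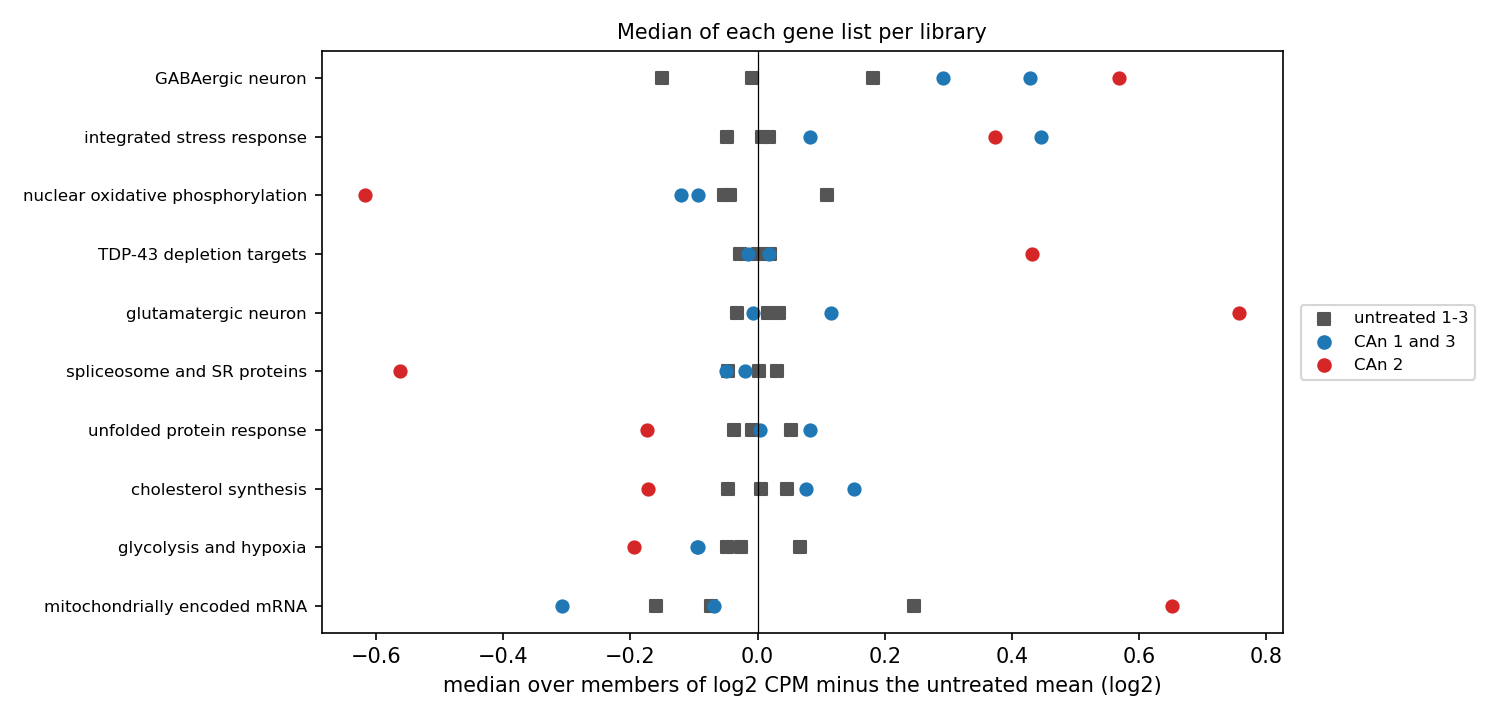
Median over the members of each called gene list of log2 CPM minus the untreated mean, with 1 point per library and lists in rows. Untreated libraries are grey squares, CAn replicates 1 and 3 blue circles and CAn replicate 2 a red circle. For the TDP-43 depletion targets CAn replicate 2 lies at 0.43 and the other CAn libraries at -0.02 and 0.02.

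The deposited factors, compared as a proxy for the effective transcript length of each gene, asked whether transcripts of different length were used. This comparison was chosen after the data were seen. Limma called 0 of 16952 genes over all 6 libraries, with 788 at an unadjusted p under 0.05 where chance gives 848, and 0 without CAn replicate 2, with 1167. The smallest adjusted p over all libraries, 0.0874, belonged to SLC2A10, a glucose transporter, and TPM1, a tropomyosin. The log2 factor of TPM1 was 0.10 in each untreated library and -0.09, -0.11 and -0.10 with CAn, and that of SLC2A10 differed by 2.47 ± 0.12 (SE). STMN2 differed by -0.22 ± 0.05 without CAn replicate 2 (limma adjusted p = 0.558), with values of 0.28, 0.17 and 0.23 untreated and 0.05 and -0.04 with CAn. POLDIP3, a target of TDP-43, differed by -0.25 ± 0.05 over all libraries (limma adjusted p = 0.833). PFKP, another target, differed the other way, by 0.32 ± 0.06 (limma adjusted p = 0.733). Of the 37 listed targets, 2 had an unadjusted p under 0.05 over all libraries and 5 without CAn replicate 2. In both fits 0 passed adjusted over the list alone (smallest limma adjusted p = 0.125 and 0.219).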

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

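The tests in this part were chosen after the results they bear on had been seen, except the edgeR splits of all 6 libraries. The prediction for those splits was set down in advance. The test on neighbouring genes was chosen after CAn replicate 2 had been seen to stand apart, but its prediction was set down before it was run.

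The deposited normalized values entered tests of gene amounts only through their factors, as offsets in an alternative added later, and 1 library drew attention there. The log2 length factor of CAn replicate 2 had an SD over genes of 0.414, above the highest untreated value of 0.238, and 16.6% of its genes lay beyond 0.5 in size. The same library had the lowest median correlation with the others. Lower depth was argued against, because with every library thinned to the same total its median correlation was still 0.9309, where the lowest of the others was 0.9815. A stronger response of the same kind was argued against too, as the only source of the deviation. Across genes, its deviation from either CAn library correlated at -0.029 on average with the change in the other, where a deviation made only of the shared change would give about 0.37. Beside another deviation in this library, a stronger response would give a smaller value, so that case stays open. A bias towards GC-rich genes is a candidate explanation. Genes on chromosomes 16, 17, 19 and 22, which are rich in GC, lay 0.629 higher (log2) in this library than genes on 4, 5, 13 and 18, against at most 0.049 in size elsewhere. These were also the chromosomes with the highest medians in this library, 0.217 to 0.471, and the lowest, -0.322 to -0.251. The prediction for this gap was written after the gap had been seen, so its size alone cannot decide. Deviations of neighbouring genes correlated at 0.171 across 15040 pairs, against at most 0.0309 in the other libraries. GC content itself was not used here, and the treatment stays open as a source of what is particular to this library.

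The 44 genes called without CAn replicate 2 rest on 2 treated libraries. Of the 10 splits of these 5 libraries into 3 and 2, 1 gave as many calls, the real one, and the highest of the others gave 12. For all 6 libraries, the 10 splits into 3 and 3 each gave 0 calls with edgeR, so 10 of 10 were as large as the real one, and the highest other was 0. With DESeq2 the real split gave 19 and the highest other 4, and with library weights 47 and 8. None of these designs can give a share under 0.05. With the authors' factors as offsets only OXCT1 passed, but the median absolute log2 fold change of the 44 genes was 99.7% of that without them (0.547 before, 0.546 after). All 44 kept their direction, and their median SE went from 0.081 to 0.101 while the median fold stayed nearly in place. Genes at an unadjusted p under 0.05 went from 1852 to 1479, and how far this shift in the adjustment, beside the larger SE, ended the calls was not tested. Shifts in estimated transcript length are thereby argued against as the source of the fold changes of these genes as a set, but not for each gene. With the offsets the log2 differences of SERF1A, SERF1B and VCAN went from 1.08, -0.95 and 0.51 to 0.50, -0.39 and 0.32. Those of PAK1, UBE4A and MVD went from -0.83, -0.54 and 0.53 to -0.59, -0.38 and 0.40, while that of FABP3 went from 0.92 to 1.06. For the genes whose differences shrank, such shifts stay open as a partial source.

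SERF1A and SERF1B, near-identical copies on chromosome 5, moved in opposite directions without CAn replicate 2. Their summed counts differed by -0.0608 ± 0.0881 (SE, log2). Reads shared between the copies are a candidate explanation, since a changed allocation of the same reads leaves the sum in place. In CAn replicate 2 SERF1A held 283 counts and SERF1B 4332, and the sums of the 3 CAn libraries were 5743, 4615 and 5922. With the authors' factors as offsets the differences shrank to 0.50 and -0.39, so a shift in estimated transcript length stays open for part of them. A biological switch between the copies would leave the sum in place as well and was not tested.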

How the results depend on the processing

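The fits added after the data were seen are those with library weights, with the authors' factors as offsets, and all alternatives without CAn replicate 2. Over all 6 libraries the count of 0 genes became 19 with DESeq2 and 47 with library weights, and 0 to 44 with 1 library left out. It stayed at 0 under every other setting, and no TDP-43 target passed in any. The replicate block gave 0 genes (438 at an unadjusted p under 0.05). Same-numbered samples correlated in their deviations at 0.0971, 0.0439 and -0.0412, where pairs of unlike number lay between -0.111 and 0.0848. The deviations of the CAn samples were taken from a mean that held CAn replicate 2, so this check cannot show or exclude pairing. The 44 calls without CAn replicate 2 became 315 with DESeq2, of which 43 were among the 44, 97 with the replicate block, 75 with the block and the gene span trend removed, and 67 for protein-coding genes alone. They became 19 with library size alone, 14 at an adjusted p under 0.01, 1 against a minimum fold of 1.5, 1 with the authors' factors, and 10 to 74 with a further library left out. The cause was not tested, except that stricter thresholds lower counts by construction. Other settings gave 43 to 54. Of the lists, 0 were called with an estimated correlation and 0 with fry in either fit. With a library left out 5 to 7 were called, and 3 to 8 where CAn replicate 2 was left out already; other settings gave 6 to 8. Without CAn replicate 2, the replicate block ended the call of the mitochondrial mRNAs (camera adjusted p = 0.0893), and it ended no other list's call in either fit. Over 21 alternatives the 31 named genes kept their direction with these exceptions: HMGCS1 went from -0.0658 to 0.3263 and SERF1B from -0.9522 to 0.03813 with 1 library left out. The correlation of fold change with gene span was 0.0079, and -0.0248 to 0.124 with 1 library left out. The count filter removed 0 genes, so the fit without it tests nothing. A trend on GC content and the comparison of genes with and without (TG)n runs, with its other repeat lengths and exons alone, were not run, as they need a genome sequence. Fits that left 1 treated library assume that it varies like the others. Depth limits what is known of genes under 10 counts, which are not listed.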

Other observations

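In this part, the tests of the deposited length factors, the splits of 5 libraries and the splits for the integrated stress response alone were chosen after the data were seen, as was the detail given on the fit without CAn replicate 2.

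MT1X, a metal-binding metallothionein from the oxidative stress list, had a log2 difference of 2.43 ± 0.64 over all 6 libraries (SE, edgeR adjusted p = 0.82 over all genes) and 1.74 ± 0.59 without CAn replicate 2, where it passed with edgeR adjusted over the list alone (adjusted p = 0.0473). The iron storage gene FTL, from the same list, differed by -0.29 ± 0.07 there (edgeR adjusted p = 0.0119 over the list alone). The glutamate receptor genes GRIA1 and GRIN2B differed by 0.28 and 0.34, the 2 of 20 listed glutamatergic markers that passed adjusted over the list alone. Of the 46 interferon-stimulated genes and nucleic acid sensors fixed beforehand, 23 could be tested. Of these, 15 were higher and 8 lower over all 6 libraries (camera adjusted p = 0.633), and 11 higher and 12 lower without CAn replicate 2. No tested member passed in either fit. A change in the untested members, such as a switch from off to on, would not be seen here. Immediate early genes of neuronal activity were lower for 14 of 18 members without CAn replicate 2 (camera adjusted p = 0.146).

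The lists called by camera at the preset correlation are not set apart from other groupings of the libraries. The real split of all 6 libraries gave 6 lists, the highest other split gave 8, and 3 of the 10 splits gave at least as many, the real one included; this design cannot give a share under 0.05. With CAn replicate 2 left out, the real split gave 7 and the highest other 9. For the integrated stress response alone, the real split of all 6 libraries gave the smallest camera p, 7.72e-06, beside 1.28e-05 in the next. Without CAn replicate 2 the smallest camera p over the 10 splits of the 5 libraries was 6.04e-15, with untreated replicate 1 set beside CAn replicate 1, and the real split gave 3.68e-11.

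Gene span, tested as planned, showed a Spearman rho across genes of 0.0079 with the log2 fold change over all 6 libraries (permutation over 15125 genes, p = 0.343). It was 0.12 without CAn replicate 2 (p = 1e-04, the smallest that 10000 permutations can give). The 25% of genes with the longest span then had a median of 0.03 and the 25% with the shortest -0.04. Genes are not independent replicates, so this p describes these libraries. For the deposited length factors, 10 of the 10 splits of the 6 libraries gave at least the 0 genes of the real one, and the highest other gave 2. With library weights the real split called 4 genes, TPM1, ATF7IP, PHLDB3 and SLC2A10, and the highest other split also 4.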
